A study of Rattus norvegicus with 12 samples.

How the data were processed

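RNA was sequenced from β-synuclein-reactive CD4+ T cells of Lewis rats that were sorted 3 days after intravenous transfer. The 12 libraries form 4 groups of 3: wild-type cells from blood, and T cell receptor transgenic cells from blood, from the meninges (the membranes around the brain) and from the brain parenchyma (the brain tissue itself). The group and the replicate number of each library came from the sample titles and characteristics. The last digit of the tissue code in the titles was 4 for the 3 parenchyma samples and 3 for the other 9 samples, and what it stands for is not given in the sources used here; all samples were treated as day 3. If the digit marks a day, every comparison with the parenchyma is also a comparison between days, and tissue and day could not be told apart. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

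The deposited values were whole-number counts per gene, with 32754 gene rows in every file, and no file held a row other than a gene. Per the submitters' processing notes, the tools named for the series were bcl2fastq 2.17.1.14, FastQC 0.11.5, STAR 2.5, featureCounts 1.5.0-p1, DESeq2 1.14.1 and R 3.4.2, with genome build rn6. Their settings, the strand setting of the counting and the gene annotation are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner could not be separated, and near-identical gene copies may share counts. Per the labels' protocols, RNA was extracted with Trizol, and both a TruSeq kit and a NEBNext low-input kit are named without saying which library was made with which. A kit that differed between groups could not be told from the group itself.

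The files list genes by Ensembl rat identifiers and do not pair them with names, and 0 lines of the reference table at hand held such an identifier. Gene names were therefore not used. The gene lists and the gene panel fixed before the data were examined (T cell activation, cytokines, chemokine receptors, markers of other cell types and the like), and the planned measure of T cell receptor segment usage, could not be tested and are not analysed here. The identifiers printed follow the rule fixed before the data were examined, without its condition on the gene symbol: the largest fold changes in each direction among genes past the threshold with a mean of at least 20 CPM (counts scaled to library size) in the higher group and no overlap between the libraries of the groups, with at most 2 printed per direction and comparison. An identifier chosen in another way is said to be so where it is printed.

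Library totals ran from 16643832 to 38601400 counts, and 12342 rows had no count in any library. Pairs of replicates within each group were compared by a chi-square test of their counts over genes, and the lowest value per degree of freedom was 14.8, so that no pair of replicates within a group agreed within sampling noise. Libraries of different groups were not compared in this way.

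Changed genes were called with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by the trimmed mean of M-values (TMM), and contrasts were tested two-sided with the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The comparisons between tissues were fitted on the 9 transgenic libraries (6 residual degrees of freedom, 11809 genes tested). The comparison of genotypes was fitted on the 6 blood libraries (4 residual degrees of freedom, 11618 genes tested). Adjusted p-values of single genes below come from these edgeR fits, and the standard error (SE) of a log2 fold change was approximated as its size divided by the square root of F. CPM values use TMM-scaled library sizes, and are given as mean ± SD over 3 libraries. Where a group had no count, a fold is a lower bound against a floor of 3 counts over the group, and the ratio of pooled counts of a gene with few counts carries an exact binomial interval at 95%. Such intervals and bounds cover counting error only. Principal components were computed on log2 CPM of the 500 most variable genes.

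The edgeR procedure was tested on simulated data in which 200 genes were changed by known folds in counts drawn from the means, totals and spread of the real libraries. Of the genes changed 2-fold, 44% were recovered in meninges against blood, 51% in parenchyma against blood and 56% in parenchyma against meninges, each among 11809 genes, and 71% in transgenic against wild-type blood among 11618 genes. Of those changed 4-fold, 86%, 86%, 81% and 97% were recovered, in the same order. None was called in the wrong direction (0 genes in each comparison), and unchanged genes called numbered 6, 7, 9 and 9.

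Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no filter on low counts, a mean of at least 50 counts, DESeq2 1.42.0, limma 3.58.1 voom with sample weights, fits on all 12 libraries or on only the groups compared, the replicate number as a block, an absolute log2 fold change above 1 as well, thinning of all libraries to 16643832 counts, and leaving out each replicate in turn. Alternatives chosen after seeing the data were removal of the 20 most abundant genes, a minimum of 10 CPM in transgenic blood, and leaving out parenchyma replicate 3 together with meninges replicate 1. The removal of mitochondrially encoded and haemoglobin genes was planned and could not be run without gene names.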

Results

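The messenger RNA of β-synuclein-reactive CD4+ T cells was profiled in 12 libraries. β-Synuclein is a neuronal protein, and T cells that recognise it can enter the brain after intravenous transfer. Wild-type cells were sequenced from blood, and transgenic cells, which carry a β-synuclein-specific T cell receptor, from blood, meninges and brain parenchyma, with 3 libraries per group. Totals were 38601400, 36457484 and 29959282 counts in wild-type blood and 21229957, 20438791 and 16848739 counts in transgenic blood. They were 23504826, 16643832 and 32843166 counts in the meninges and 19054156, 21840045 and 27761421 counts in the parenchyma. The number of genes with at least 1 count ran from 14409 in transgenic blood replicate 3 to 17095 in parenchyma replicate 3. The 20 most abundant genes took between 8.95% and 12.5% of a library's counts.

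The libraries separated by group on the first principal component, which held 72.1% of the variance of the 500 most variable genes. Its scores lay between -48.9 and -46.5 in wild-type blood, between -29.2 and -24.4 in transgenic blood, between 4.16 and 23.6 in the meninges and between 32.8 and 91.0 in the parenchyma. Log2 CPM correlated across genes at 0.984 or more within wild-type blood, transgenic blood and meninges, and at 0.941 to 0.973 within the parenchyma, the group with the widest spread. These correlations are over genes, which are not independent replicates.

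**Figure D1:**
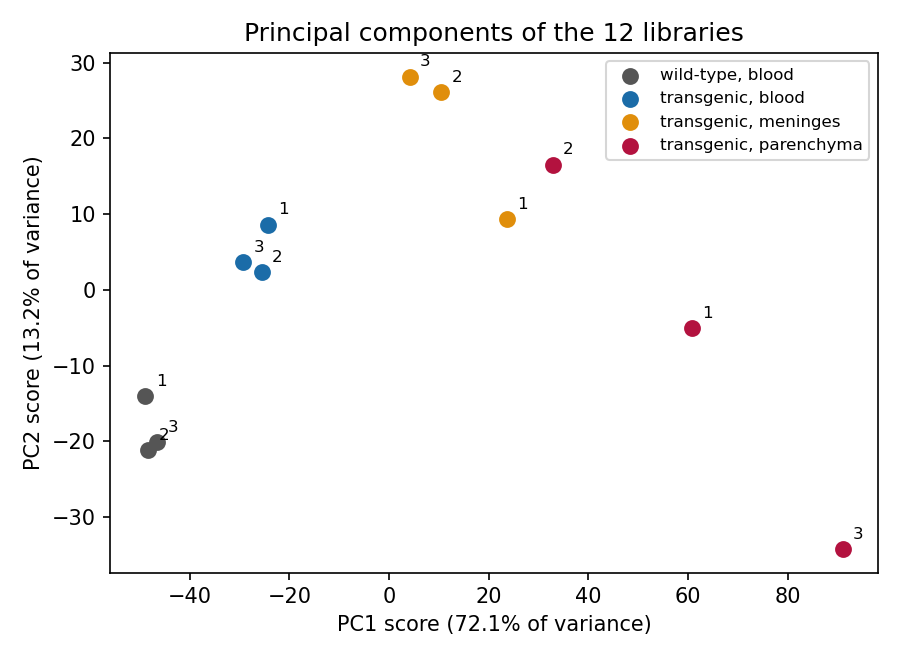
Scores of the 12 libraries on the first principal component (horizontal, 72.1% of the variance) and the second (vertical, 13.2%), from log2 CPM of the 500 most variable genes. Each point is a library with its replicate number, and the parenchyma libraries are the most spread out, from 32.8 to 91.0 on the horizontal axis.

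The comparison of transgenic cells from meninges and blood asked how cells at the border of the brain differed from those in circulation. In the meninges, 769 of 11809 tested genes changed, of which 562 were higher and 207 lower than in blood. The genes that rose took 8.67% ± 0.903 of the counts in the meninges and 3.99% ± 0.309 in blood (SD, n = 3), and their median rise was 2.35-fold. The genes that fell took 2.09% ± 0.0454 of the counts in the meninges and 3.70% ± 0.137 in blood, with a median fall of 1.76-fold. Such shares and median folds, here and in the other comparisons, are of genes called in the same libraries, which favours large values. They are not compared between contrasts, since the lists differ. Rises of more than 8-fold were seen in 82 genes and falls of that size in 1 gene. ENSRNOG00000012467 rose from 3.11 ± 0.663 CPM in blood to 861 ± 491 CPM in the meninges (log2 fold change 8.13, SE 0.57, adjusted p = 6.86e-05), with the lowest meningeal library at 299 CPM. ENSRNOG00000017348 rose from 0.111 ± 0.120 to 28.7 ± 15.4 CPM (log2 fold change 8.05, SE 0.79, adjusted p = 0.000429). It had 6 counts over the 3 blood libraries, and the ratio of pooled counts was 279.8-fold (95% interval 128 to 763). Its log2 fold change was 7.43 without blood replicate 2 and 9.08 without blood replicate 3. ENSRNOG00000014205 fell from 281 ± 43.6 to 44.6 ± 5.09 CPM (log2 fold change -2.65, SE 0.43, adjusted p = 0.00554), and ENSRNOG00000001011 fell from 48.8 ± 8.05 to 12.2 ± 2.45 CPM (log2 fold change -2.0, SE 0.26, adjusted p = 0.00176). Values in the meninges and blood did not overlap in 31.6% of the tested genes, where chance gives 10% for 3 libraries against 3. The count of changed genes was 1314 with DESeq2 (849 higher, 465 lower), 1791 with limma-voom (1003 higher, 788 lower), 1255 in a fit of only these groups (789 higher, 466 lower) and 427 with an absolute log2 fold change above 1 as well. It was 359 without blood replicate 2, 411 without blood replicate 3, 346 without meninges replicate 2 and 400 without meninges replicate 3.

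The comparison of parenchyma and blood asked the same of cells inside the brain tissue. The parenchyma samples alone carry the digit 4 in their titles, and if it marks a day, the parenchyma contrasts also compare days. Here 4143 of 11809 genes changed, 2211 higher and 1932 lower. The genes that rose took 21.8% ± 1.00 of the counts in the parenchyma against 10.4% ± 0.295 in blood (SD, n = 3). The genes that fell took 17.0% ± 0.566 in the parenchyma against 29.5% ± 0.118 in blood. The median rise was 2.16-fold and the median fall 1.76-fold. More than 8-fold changes were uneven in direction, with 458 genes higher and 26 lower. Such counts, here and in the other contrasts between tissues, include genes near 0 in the lower group, whose folds rest on few counts. Genes near 0 in blood can pass the filter through the parenchyma alone. The counts were not repeated without parenchyma replicate 3. ENSRNOG00000002919 had 0 counts in the blood libraries and 60.0 ± 66.5 CPM in the parenchyma, between 16.2 and 136 CPM per library, which was at least 1330-fold higher against a floor of 3 counts over the blood group (adjusted p = 0.00135). ENSRNOG00000011016 also had 0 counts in blood and was at least 777-fold higher against the same floor (adjusted p = 0.0113), at 34.0 ± 48.8 CPM, with libraries from 0.572 to 90.1 CPM. Without parenchyma replicate 3, these bounds were 421-fold for ENSRNOG00000002919 and 110.3-fold for ENSRNOG00000011016. ENSRNOG00000014205, which fell in the meninges, averaged 15.6 ± 9.46 CPM in the parenchyma. Its log2 fold change against blood was -4.15 (SE 0.46, adjusted p = 0.000182). ENSRNOG00000002652 fell from 290.0 ± 24.0 CPM in blood to 22.9 ± 12 CPM (log2 fold change -3.66, SE 0.36, adjusted p = 9.78e-05). Parenchyma and blood values did not overlap in 46.3% of the tested genes, where chance gives 10%. With an absolute log2 fold change above 1 as well, 1926 genes passed. A fit of only these groups called 3336 genes (1717 higher, 1619 lower). The main fit uses a common spread for the 9 transgenic libraries, although the groups differed in spread. The median SD of log2 CPM between replicates was 0.232 in the parenchyma, 0.201 in transgenic blood and 0.174 in the meninges. Counts of changed genes are therefore not compared between contrasts.

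**Figure D2:**
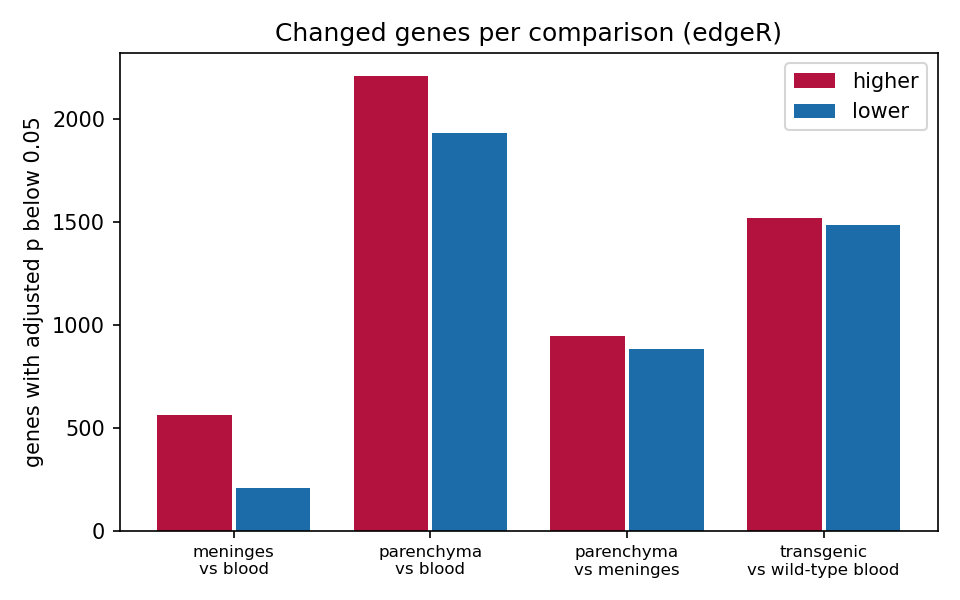
Number of genes with an edgeR adjusted p below 0.05 (vertical axis) in each comparison, with separate bars for genes higher and lower in the group named first. The bars run from 207 genes lower in meninges than in blood to 2211 genes higher in parenchyma than in blood.

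Parenchyma and meninges were compared directly to ask whether cells of the brain compartments differed from each other. The contrast called 1828 of 11809 genes, 945 higher and 883 lower in the parenchyma. The balance of directions was not stable: lower genes outnumbered higher ones in 10 of 22 other settings. Among them were the fit of only these groups (584 higher, 687 lower) and omission of meninges replicate 1 (504 and 599), 2 (325 and 405) or 3 (336 and 473). Genes of at least 10 CPM in transgenic blood (515 and 690) were another such setting. That minimum drops genes low in blood, which by itself favours lower calls in the parenchyma. Genes higher in the parenchyma took 9.02% ± 0.937 of its counts and 4.55% ± 0.187 of those of the meninges (SD, n = 3), with a median rise of 2.31-fold. Genes lower in the parenchyma took 11.6% ± 0.297 and 18.4% ± 0.169, with a median fall of 1.70-fold. More than 8-fold differences numbered 193 higher and 5 lower in the parenchyma, and were not recounted without parenchyma replicate 3. ENSRNOG00000008816 averaged 332 ± 543 CPM in the parenchyma and 0.827 ± 0.614 CPM in the meninges (log2 fold change 8.54, SE 1.93, adjusted p = 0.0187), and ENSRNOG00000020533 averaged 34.7 ± 57.7 and 0.0995 ± 0.147 CPM (log2 fold change 8.39, SE 2.05, adjusted p = 0.0244). Both averages rested mostly on parenchyma replicate 3, at 959 and 101 CPM. Without it, the log2 fold changes were 4.41 (adjusted p = 0.0146) and 3.76 (adjusted p = 0.0270). Over the settings that gave one, the adjusted p ranged from 6.37e-06 to 0.0973 for the first gene and from 0.00694 to 0.102 for ENSRNOG00000020533. DESeq2 gave no adjusted p for ENSRNOG00000020533. Both genes missed the threshold when any 1 meningeal library was left out. The log2 fold change of ENSRNOG00000008816 was then 8.78 without meninges replicate 1, 8.15 without replicate 2 and 8.74 without replicate 3, and that of ENSRNOG00000020533 was 10.36 without meninges replicate 1, 7.99 without replicate 2 and 7.76 without replicate 3. ENSRNOG00000009884 was lower in the parenchyma, at 30.7 ± 11.8 CPM against 207 ± 95.9 CPM in the meninges (log2 fold change -2.75, SE 0.36, adjusted p = 0.00182), and so was ENSRNOG00000020457, at 6.83 ± 1.83 against 42.1 ± 5.12 CPM (log2 fold change -2.61, SE 0.21, adjusted p = 0.000252). The count of changed genes was 1271 in a fit of only these groups. It was 1103 without meninges replicate 1, 730 without replicate 2 and 809 without replicate 3. It was 830 with an absolute log2 fold change above 1 as well, and, in settings chosen after the data were seen, 1205 among genes of at least 10 CPM in transgenic blood and 1031 without parenchyma replicate 3 and meninges replicate 1.

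Genes that changed in both brain compartments mostly changed in the same direction. Called in both against blood were 482 genes higher and 186 genes lower, and 6 genes were called in opposite directions. Independent lists of these lengths would share 105 and 33.9 genes. In 20 simulations the groups, blood included, were drawn without differences between them, and both comparisons shared the drawn blood libraries. The shared calls averaged 0.15 genes. The simulated lists for meninges and parenchyma held only 1 and 0.65 genes on average. The number of simulated shared calls thus says little about lists as long as those observed. Log2 fold changes against blood correlated across genes at r = 0.779 (Spearman's rho 0.688), and the simulated unchanged groups gave 0.510, because both comparisons use the same blood libraries. The covariance was 0.823 against 0.0333 in the simulations, a difference of 0.790. Genes nearly absent from the real blood libraries need not be so in the drawn ones. The observed covariance also depended on the scale, at 0.366 on log2(CPM + 0.5), for which no simulated value was computed. The difference is therefore not read as the size of a shared change. With the 3 blood libraries divided between the comparisons, 1 for one and 2 for the other, in a calculation on log2(CPM + 0.5) chosen after the data were seen, r lay between 0.624 and 0.690 and the covariance between 0.331 and 0.352 over 6 divisions, against 0.738 and 0.366 with all blood libraries in both. The shared calls were not recomputed with divided controls, and part of their excess may come from the shared libraries. Shared calls in the same direction, 668 with all libraries, were 335 without blood replicate 2, 380 without blood replicate 3, 330 without meninges replicate 2 and 373 without meninges replicate 3.

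**Figure D3:**
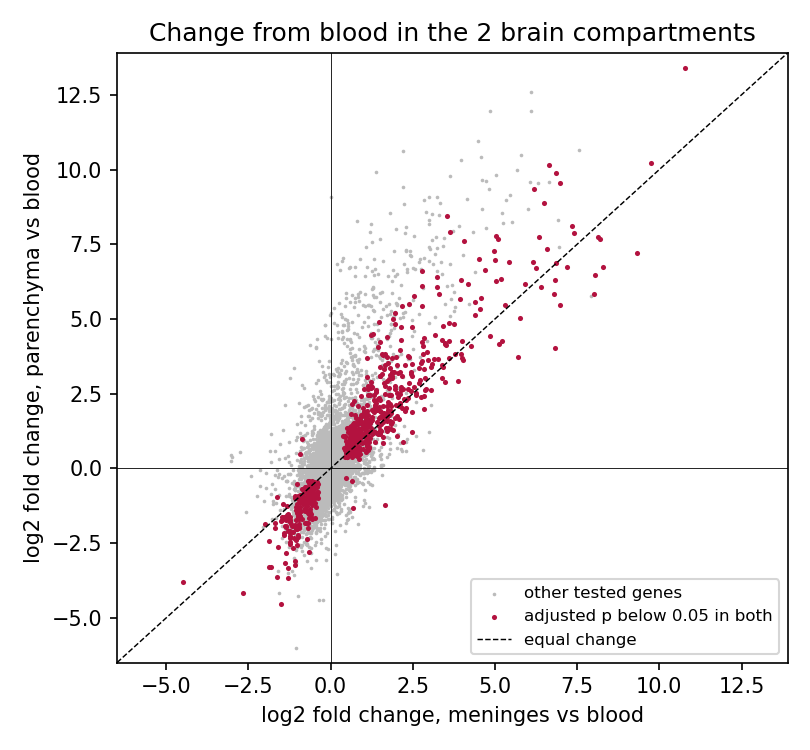
Log2 fold change of each of the 11809 tested genes in meninges against blood (horizontal) and parenchyma against blood (vertical). Points in red had an adjusted p below 0.05 in both comparisons, grey points are the other genes, and the dashed line marks equal change; most of the red points lie in the upper right (482 genes) or lower left (186 genes).

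Taken by the 3 contrasts between tissues, 4428 genes were called at least once. Stepwise changes, called from blood to meninges and again from meninges to parenchyma, were found in 150 genes that rose at both steps and 83 that fell at both. A further 321 genes were higher and 103 lower in both brain compartments than in blood with no call between the compartments. In 711 genes the parenchyma was higher than both other tissues and in 625 it was lower than both, with no call between meninges and blood. Another 1016 genes were higher and 1117 lower in the parenchyma than in blood with no other call. The meninges stood above both other tissues in 59 genes and below both in 10. A missing call does not show that levels were equal. For the genes higher in the parenchyma than in blood, the level in the meninges lay at a median of 0.440 of the way from blood to parenchyma on the log2 scale (interquartile range 0.226 to 0.654), and for the genes that were lower at 0.407 (0.229 to 0.585). It lay between the levels of blood and parenchyma in 85.6% and 88.3% of these genes. Selection of the genes and the shared blood libraries favour such values: in 20 simulations with the meninges unchanged from blood, the median position averaged 0.0406 and 0.0516, and 57.4% and 59.0% of the called genes lay between.

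Genes nearly absent from transgenic blood, with at most 3 counts in every blood library and a mean of at least 5 CPM in the parenchyma, numbered 76. They held 0.0576%, 0.0180% and 0.317% of the counts of parenchyma replicates 1, 2 and 3, 0.0111%, 0.00774% and 0.00469% of those of meninges replicates 1, 2 and 3, and between 0.000316% and 0.000386% in transgenic blood. The limit of 5 CPM is on the group mean, so that 1 library can carry a gene past it. Of the 76 genes, 71 were highest in parenchyma replicate 3 and 51 were below 1 CPM in replicate 2. The number 76 thus rests largely on replicate 3, and it was not recomputed without that library. By the same limits, 3 genes were present in the meninges and nearly absent from transgenic blood. Present in the parenchyma and nearly absent from the meninges were 6 genes. In the other direction, 0 genes present in transgenic blood were nearly absent from the parenchyma or from the meninges. Depth was not taken into account in the limit of 3 counts. The deepest library held 27761421 counts in the parenchyma, 32843166 in the meninges and 21229957 in transgenic blood. Absence was thus judged more strictly in the brain compartments, and the numbers of the directions are not on an equal footing.

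**Figure D4:**
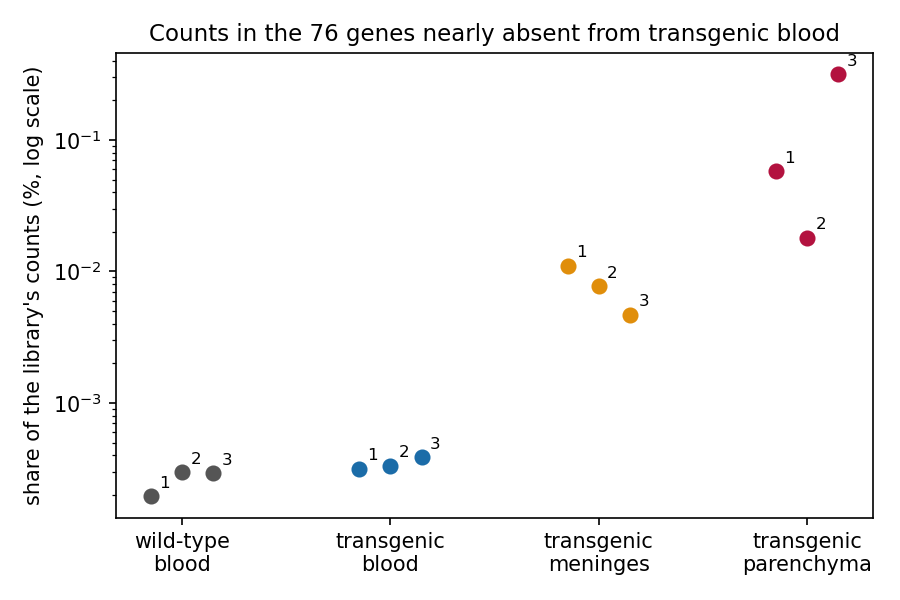
Share of each library's counts, in percent on a log axis, held by the 76 genes with at most 3 counts in every transgenic blood library and at least 5 CPM on average in the parenchyma. Each point is a library with its replicate number; parenchyma replicate 3 is highest, at 0.317%.

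Transgenic and wild-type cells were compared in blood, the tissue in which both genotypes were sequenced. Of 11618 tested genes, 3002 changed, 1518 higher and 1484 lower in transgenic cells, and in 6 of 16 other settings the lower genes were the more numerous. The genes that were higher took 14.4% ± 1.61 of the counts in transgenic and 8.13% ± 0.742 in wild-type cells (SD, n = 3), with a median rise of 1.88-fold. The genes that were lower took 8.40% ± 0.872 and 14.3% ± 1.18, with a median fall of 1.84-fold. More than 8-fold differences were found in 57 genes higher and 85 genes lower in transgenic cells. ENSRNOG00000057643 averaged 25.1 ± 6.17 CPM in transgenic and 0.516 ± 0.225 CPM in wild-type blood (log2 fold change 5.59, SE 0.32, adjusted p = 7.04e-06). ENSRNOG00000048468 averaged 0.328 ± 0.0774 CPM in transgenic and 343 ± 57.2 CPM in wild-type blood (log2 fold change -10.02, SE 0.25, adjusted p = 4.66e-08), and the ratio of its pooled counts was 1081-fold (95% interval 692 to 1795). ENSRNOG00000049577 had 3 counts over the transgenic blood libraries and 45.4 ± 9.49 CPM in wild-type blood, a ratio of 907-fold with a 95% interval of 310 to 4398 (adjusted p = 1.01e-06). Its log2 fold change was -9.67, and -10.51 without transgenic blood replicate 2, which held 2 of the 3 counts. Values of the genotypes did not overlap in 44.3% of the tested genes, where chance gives 10%. The count was 1789 without transgenic blood replicate 1 and 1298 with an absolute log2 fold change above 1 as well. Wild-type libraries were deeper than transgenic blood libraries, and the kit used for each is not given in the sources used here.

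Few genes were present in one genotype and nearly absent from the other in blood. The transgenic side had 1 such gene, ENSRNOG00000012906, which is named after its values were seen. It had 0 counts in every wild-type library and 13.7 ± 1.30 CPM in transgenic blood, at least 476-fold higher against a floor of 3 counts over the wild-type group (adjusted p = 5.70e-06), and stood at 14.4 ± 1.60 CPM in the meninges and 15.6 ± 3.04 CPM in the parenchyma. The wild-type side had 6 such genes, ENSRNOG00000049577 among them, with means from 5.17 to 45.4 CPM in wild-type blood. The limit of 3 counts per library was not scaled to depth. Absence was thus judged more strictly in the deeper wild-type libraries, and the numbers 1 and 6 are not on an equal footing. None of the 6 had more than 8 counts in any meningeal or parenchymal library, all of which were transgenic.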

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

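Settings chosen after the data were seen were the removal of the 20 most abundant genes, the minimum of 10 CPM in transgenic blood, and the joint omission of parenchyma replicate 3 and meninges replicate 1. Counts within 1.5 times of the reported one are not listed except for the block. Meninges against blood gave 769 genes, against 1314 with DESeq2, 1791 with limma-voom, 1255 in a fit of only these groups, 427 with an absolute log2 fold change above 1 as well, and 346 to 952 when 1 replicate was left out. Of the 769 genes, 759, 761 and 760 were called in the same direction by DESeq2, by limma-voom and in the fit of only these groups. The share of calls that were higher in the meninges was 73.1%, against 64.6%, 56.0% and 62.9% in these settings. With an absolute log2 fold change above 1 as well, parenchyma against blood gave 1926 genes (main 4143), parenchyma against meninges 830 (main 1828) and transgenic against wild-type blood 1298 (main 3002), by construction of the stricter limit. Lower genes outnumbered higher ones in 0 of 22 settings for meninges against blood and 1 of 22 for parenchyma against blood (the CPM minimum, 1442 higher and 1474 lower). They did so in 10 of 22 for parenchyma against meninges and 6 of 16 for transgenic against wild-type blood. The CPM minimum is set on transgenic blood, so it removes genes that rise from low levels there and by itself favours lower calls. Parenchyma against meninges gave 1205 with the CPM minimum, which tests 8002 genes, and 1031 with the joint omission, which leaves fewer samples. Omission of 1 replicate gave 3298 to 4416 genes for parenchyma against blood, 730 to 2159 for parenchyma against meninges, 1789 to 2906 for transgenic against wild-type blood, and 330 to 804 shared calls of meninges and parenchyma (main 668). For the differences between tools and between fits the cause was not tested. DESeq2 size factors, no filter on low counts, a mean of at least 50 counts and thinning to 16643832 counts each moved no count of changed genes in the 4 comparisons by more than 1.5 times, and no scaling moved the median of all genes by 0.1 or more on the log2 scale. Of 320 results for the genes picked by the printing rule, 309 kept direction and threshold and 0 reversed. The other 11 kept the direction and missed the threshold, all of them of ENSRNOG00000008816 and ENSRNOG00000020533 in parenchyma against meninges. Settings that gave a gene no adjusted p, such as DESeq2 for ENSRNOG00000020533, are not among the 320. ENSRNOG00000010661, picked by the rule but not described above, is included, and ENSRNOG00000012906 is not. Kept directions were largely built in, because the rule chose these genes in the same libraries for their large folds. The limit on the log2 fold change reuses the main fit, and some omissions removed a library outside the contrast.

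The labels do not say whether samples of the same number share an animal or a transfer. The data neither showed nor excluded that such samples were paired, and some best matches by number arise without pairing. Deviations of same-numbered libraries from their group means correlated at 0.253, 0.266 and 0.053 for transgenic blood with meninges, between -0.139 and 0.020 for blood with parenchyma and between -0.312 and 0.024 for parenchyma with meninges, and 4 of the 9 transgenic libraries matched a library of their own number best. With the number as a block, the counts were 674, 3671, 1407 and 3126 for meninges against blood, parenchyma against blood, parenchyma against meninges and transgenic against wild-type blood, and 576 shared calls. Gene-list tests, receptor segment usage and the removal of mitochondrially encoded and haemoglobin genes were not run, for lack of gene names. In the genotype comparison the fit of only the groups compared is the one reported.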

Other observations

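Tests of RNA from another source, of dilution and of a common axis were chosen after the results they bear on were seen. The counts over other splits, the test of preparation and the thinning of libraries were set before, but how the thinned count would be read was set after it was seen.

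To see how far each brain library carried the difference between parenchyma and blood, genes were called without it and then measured in it, relative to the mean of transgenic blood on log2(CPM + 0.5). The blood libraries serve both steps. In parenchyma replicates 1, 2 and 3 the genes called higher had medians of 1.00, 0.72 and 0.99, and the genes called lower had medians of -0.85, -0.66 and -0.75. In meninges replicates 1, 2 and 3 the medians were 0.42, 0.41 and 0.36, and -0.27, -0.37 and -0.32. In wild-type blood, for the 2211 and 1932 genes called with all transgenic libraries, they lay between -0.02 and 0.04 and between -0.10 and -0.02.

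A first pattern is that the 76 genes nearly absent from transgenic blood differed between the parenchyma libraries. Of these genes, 71 were highest in parenchyma replicate 3, and the median log2 ratio of replicate 3 to replicate 2 was 5.55. The set was chosen by its mean over the same 3 libraries, which admits genes high in only 1 of them. Part of this difference is therefore built in by the choice. RNA of a single other source in differing amounts would give all of the genes a common ratio. Their ratios had an interquartile range of 2.77 on the log2 scale, and the highest of 100 draws with a common ratio and the spread of the fit was 1.38. This does not exclude a single source, because 51 of the 76 genes were below 1 CPM in replicate 2 and the spread of the draws was assumed. A single source stays open. Several sources of RNA from other cells of the brain, and genes switched on in the T cells themselves, also stay open and were not tested, since the genes could not be named.

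A second pattern is the fall of 1932 genes from blood to parenchyma, for which dilution of T cell RNA by the RNA of other cells is a candidate explanation. If a single source carried the 76 genes and diluted the rest, replicate 2, with 0.0180% of counts in those genes against 0.317% in replicate 3, could show a median change no lower than -0.08, and replicate 1 no lower than -0.29. The 76 genes were chosen by their mean over the same parenchyma libraries, which builds part of the difference between replicates into these limits. In genes called without the library in question, the observed medians were -0.66 and -0.85, beyond these limits by more than 2 times the SD of 0.0239 among the transgenic blood libraries. This argues only against dilution by a single such source, and only as far as the limits hold. Dilution by several sources that carry these genes in differing amounts is not bounded by the test and stays open. Dilution by RNA that lacks the 76 genes was not tested, and a difference between tissues, which the design names, stays open. So does a difference in day, if the title digit of the parenchyma samples (4, against 3 in the others) marks one. A difference in library kit between the tissues also stays open, because the kit of each library is not given in the sources used here.

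A further pattern is the difference of 3002 genes between transgenic and wild-type blood. Deeper sequencing of the wild-type libraries as the whole cause is argued against by thinning, after which 2793 genes were called. A difference in preparation or run between the wild-type and transgenic libraries cannot be told apart from the genotype, because 0 wild-type libraries came from a tissue other than blood and the kit of each library is not given in the sources used here. The genotype stays among the open explanations, as do differences in how the cells were obtained.

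Chance in the assignment of libraries to groups could not be tested at a 0.05 level, since 6 libraries make 10 splits and the share of splits is never below 0.1. In fits of only the groups compared, the real split gave 1255 genes for meninges against blood, 3336 for parenchyma against blood, 1271 for parenchyma against meninges and 3002 for transgenic against wild-type blood. The highest count among the other 9 splits was 0 in each case, and 1 of the 10 splits, the real one, gave as many genes. Each of the other splits mixes libraries of both groups, so that any real difference widens the spread and lowers the count. The counts of 0 therefore say little about chance.

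The order of the groups along the first principal component raised the hypothesis that the genotype difference in blood and the difference between parenchyma and meninges run along a common axis. These contrasts share no library. Across 11347 genes their log2 fold changes correlated at r = -0.066 (Spearman's rho -0.040), and genes are not independent replicates. Of 540 genes called in both contrasts, 270 changed in the same direction and 270 in opposite directions, where independent lists would share 207 and 209. Of the 500 most variable genes, on which the component was computed, only 211 were tested in both contrasts, with r = 0.025. Most of the genes behind the component thus lay outside the test. The result was negative for the genes that could be tested.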
